A study of Mus musculus with 4 samples.

How the data were processed

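Gene expression was measured by RNA sequencing in 4 livers of wild-type mice with acute-on-chronic liver failure, 2 given saline and 2 given baicalein. Per the labels' protocols, total RNA was extracted with a commercial kit and libraries were made with a SMARTer mRNA kit. Per the submitters' processing notes, the genome build was mm10, and the aligner and the counting tool are not given in the sources used here. The authors deposited 1 table for the whole series with a gene ID, symbol, position and length, and for each liver a whole-number read count per gene and an FPKM value (reads scaled by gene length and library total). Each column was tied to a liver by its name, which matches the title of 1 sample, and groups came from the treatment labels. The positions in the table are of a build not given in the sources used here: of 21851 gene IDs also found in the GENCODE M21 annotation of mm10, 514 had the same start and end. Of these IDs, 21723 are protein-coding genes there. Positions are therefore printed as the table gives them and were not mixed with mm10 coordinates. The deposited counts were used as they stood for every test except an alternative fit with FPKM-implied counts, named below. The deposited FPKM were used only for that fit and to check the counts. For the check, the count that the FPKM, the length and the library total imply was computed for each gene and liver, with a tolerance of 1%.

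The table holds 21959 gene IDs, of which 5661 had no count in any liver. Genes with enough counts for the design (filterByExpr) were kept, which left 12657. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, baicalein against saline, no other covariate, two-sided), with Benjamini-Hochberg adjustment over the 12657 genes and a threshold of 0.05. The common biological coefficient of variation was 0.289. TMM factors were 0.963, 0.981, 0.985 and 1.07 for saline 1, saline 2, baicalein 1 and baicalein 2, and the median log2 fold change of all tested genes was 0.01. An exact permutation test of 2 against 2 livers has too few arrangements to pass 0.05, so the p-values rest on the spread shared between genes. Means and SDs are of CPM, that is counts scaled by the normalised library size (n = 2 in each group). For genes with no count in a group, a fold is a lower bound against 3 counts in each liver of the group. With 1 to 3 counts over the group, a ratio is given with its exact 95% counting interval. Such bounds and intervals cover counting error only. Total counts of 13976440 to 18731616 put 3 counts at 0.150 to 0.219 CPM in a single library.

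Before the data were examined, 36 gene lists of pathways, cell types and stress responses were fixed, together with the rule for naming genes. The rule takes the 10 largest increases and the 10 largest decreases past the threshold, with a mean CPM of at least 5, no overlap between groups and a symbol that is not a predicted gene's, then 17 fixed genes of macrophages, fibrosis and liver function, and from each list the 4 members of smallest p and any member past the threshold. Each list was tested with camera in limma 3.58.1 (preset correlation of 0.01), camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the 36 lists. With an estimated correlation camera rests on the residual degrees of freedom, which are few with 4 livers, so it has low power here. Members were counted at the threshold adjusted over all genes and adjusted over the list alone. Trac, Ighm, Igkc and Xist of these lists are not among the table's gene IDs. Further lists of skeletal muscle (2 lists), smooth muscle, Y-linked, X-linked escape, male-biased liver, female-biased liver and clock output genes were written after first results had been seen. KEGG pathways named in the deposited table were tested for enrichment with a one-sided Fisher exact test against the 5530 tested genes that carry a pathway.

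The fit was tested on simulated data with the real means and library sizes. Of 12320 simulated genes, 99 were changed by a log2 fold of 1, of which 21.2% were called, and 96 by a log2 fold of 2, of which 70.8% were called. Of 12125 unchanged genes 0.231% were called. Unchanged genes far outnumbered changed ones, so the share of false calls among all simulated calls was above the threshold of 0.05. Far fewer genes were changed than were called in the real data, so these shares do not carry over to it. Of 20 simulated lists without a shift, 0 passed 0.05 with camera, and the p of a simulated list with a shift was 2.08e-07. Simulated genes were drawn independently of each other. The simulated lists therefore do not show how camera with its preset correlation behaves where members of a list are correlated.

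The alternatives were size factors of the median-of-ratios kind, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean CPM of at least 1, fold thresholds, a fit with the replicate number as a block, and each liver left out in turn. After the data had been seen, a block that pairs the livers crosswise, the FPKM-implied counts of 3 genes and the directions in single pairs of livers were added. DESeq2 was not used for the gene lists. Some genes that the naming rule picks are not reported here. No measurement column was left out for want of a sample, and no raw reads were used.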

Results

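RNA was sequenced from 4 livers of wild-type mice with acute-on-chronic liver failure (ACLF), a model in which acute injury is added to chronic liver disease. The mice of 2 livers received saline and those of the other 2 received baicalein, a flavone found in the root of Scutellaria baicalensis. The labels give no dose, time of collection or sex of the animals, and no healthy or TREM2-deficient liver was analysed here. They number the livers but do not say that each came from its own animal, so the p-values measure only the spread between these samples, which may be technical in part. The deposited counts summed to 17673137 in saline 1, 13976440 in saline 2, 14766061 in baicalein 1 and 18731616 in baicalein 2, and 14409 to 15530 genes had at least 1 count. Within a group the counts of the 2 livers differed by more than sampling noise. The chi-square per degree of freedom was 24.8 for saline and 19.7 for baicalein, against 121 to 148 between groups, so neither pair was treated as copies of 1 library. Correlations of log2 CPM over genes ran another way, at 0.938 and 0.940 within the groups, 0.955 for saline 2 with baicalein 1, 0.941 for saline 1 with baicalein 2, and 0.897 and 0.908 for the other pairs across groups. The chi-square does not tell separate animals from separate preparations of a tissue.

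Baicalein livers and saline livers differed most in genes that mouse liver expresses by sex. Mup7 (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475), a major urinary protein gene, fell from 6622 ± 572 CPM (SD, n = 2) with saline to 3.90 ± 0.223 CPM (SD, n = 2) with baicalein (log2 fold change -10.73, SE 0.18, adjusted p = 1.44e-08). Elovl3, a fatty acid elongase with male-biased liver expression, fell from 396 and 389 CPM in the saline livers to 2.54 and 1.95 CPM in the baicalein livers (log2 fold change -7.45, SE 0.17, adjusted p = 5.06e-08). Of 12657 genes tested, 968 were higher and 1000 lower with baicalein at adjusted p below 0.05, of which 381 and 244 changed at least 2-fold.

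Among the 10 largest increases were Cyp2b13, Cyp3a44, Cyp3a41a, Cyp3a41b, Sult2a2, Lypd11, Sult2a1, Sult2a5 and Cyp3a16, which except for Lypd11 encode enzymes that act on steroids, drugs or other small molecules. Of these, 6 had no count in either saline liver, so their folds are lower bounds. The floor was taken as 3 counts in each saline liver. Against it, Cyp3a44 was at least 301-fold higher with baicalein, Cyp3a41a at least 289-fold and Cyp3a41b at least 174-fold. Lypd11 was at least 155-fold, Sult2a5 at least 130-fold and Cyp3a16 at least 120-fold higher. Cyp2b13 had 1 count with saline against 10808 with baicalein, a ratio of 9601 with a 95% counting interval of 1723 to 379251. The 10 largest decreases were in Ddx3y, Mup7, Cyp4a12b, Eif2s3y, Mup14, Cyp4a12a, Kdm5d, Elovl3, Mup8 and Mup12. Ddx3y, a Y-linked RNA helicase gene, had 464 counts with saline and none with baicalein, at least 87.1-fold lower. Cyp4a12b fell from 4721 counts to 3, a ratio of 1772 with a counting interval of 606 to 8593. Members of the Mup, Cyp2b, Cyp3a, Cyp4a12 and Sult2a families are near-identical, and how the authors counted reads shared between copies is not given in the sources used here, so the values of single members are uncertain. Mup14, Cyp4a12a, Mup8 and Mup12 passed with all 4 livers but not with each liver left out. Their adjusted p reached 0.274 for Mup14 without baicalein 1 or 2, 0.219 for Cyp4a12a and 0.110 for Mup8 without saline 1 or 2, and 0.159 for Mup12 without any 1 of the 4. With the replicate number as a block, Cyp2b13, Sult2a2, Sult2a1 and Eif2s3y did not pass either (adjusted p = 0.0846, 0.0839, 0.0818 and 0.0580), nor did Cyp4a12a and Mup12.

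Across all tested genes, 59.2% had no overlap between the groups, where chance gives 33.3%. Fewer genes were called when any 1 liver was left out, which also leaves fewer degrees of freedom. A call lost in this way, here and below, therefore does not by itself show that the difference was absent. Of the 1968 called genes, 1965 to 1968 kept their direction with a liver left out. Those fits share livers with the main fit, so the directions are not a separate test.

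**Figure D1:**
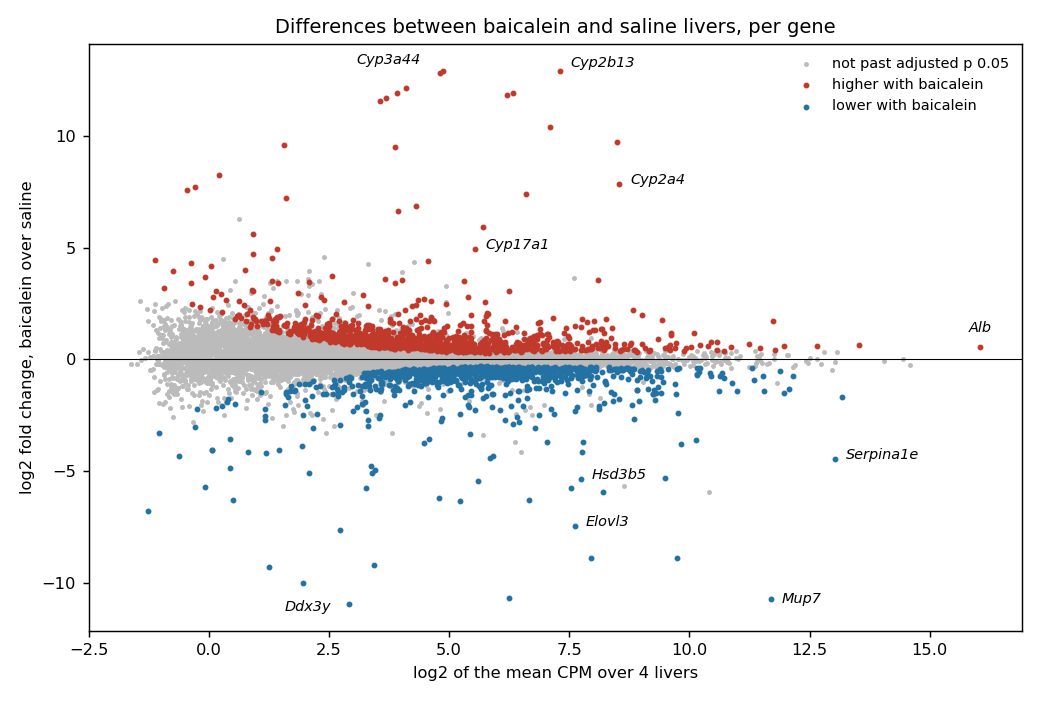
Each point is 1 of the 12657 tested genes, with the log2 of its mean CPM over the 4 livers on the horizontal axis and its log2 fold change, baicalein over saline, on the vertical axis. Red points are the 968 genes higher and blue points the 1000 genes lower at adjusted p below 0.05, and sex-biased liver genes such as Cyp2b13 and Mup7 lie farthest from 0.

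Genes of the Y chromosome separated the groups completely. Ddx3y, Kdm5d, Eif2s3y and Uty together had 820 counts in saline 1 and 836 in saline 2, against 2 in baicalein 1 and 1 in baicalein 2. Of the 9 tested members of the list of sex-linked and sex-biased liver genes, 7 fell and 2 rose, and the same numbers when adjusted over the list alone. The list passed (camera, down, adjusted p = 2.02e-04; adjusted p = 0.407 with an estimated correlation). Cyp2b9, female-biased in mouse liver, was among those that rose, and Cyp2d9, a male-biased P450, fell from 1682 ± 68.0 CPM to 121 ± 3.95 CPM (log2 fold change -3.79, SE 0.11). Xist is not among the gene IDs of the table. Lists of male-biased and female-biased liver genes were then written after these values had been seen. In them 12 of 13 male-biased genes fell, Mup20 (log2 fold change -5.92) being the exception at an adjusted p of 0.05, and 14 of 14 female-biased genes rose. With each liver left out 11 of the 12 and at least 13 of the 14 kept their calls, and with the replicate number as a block 11 and 12. Cyp2a4 rose from 3.14 ± 0.213 to 742 ± 134 CPM and Slc22a26 from 1.14 ± 0.0353 to 192 ± 2.93 CPM. Hsd3b5 fell from 418 ± 26.4 to 10.3 ± 1.01 CPM and Gstp1 from 2071 ± 87.8 to 170 ± 5.02 CPM. Cyp2b9 did not pass without baicalein 1 or baicalein 2 (adjusted p up to 0.224). Since both livers of a group had the same Y-linked pattern, treatment and this pattern cannot be told apart in any comparison given here. The Y-linked counts argue against livers of the same sex in both groups. A rise or fall with baicalein, as worded here, therefore cannot be told apart from a difference by sex.

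Clock genes moved in opposite directions by arm of the clock. Arntl, Npas2 and Clock, which encode activators of the circadian transcription loop, fell, with log2 fold changes of -1.89 (SE 0.17), -4.15 (SE 0.58) and -0.91 (SE 0.20). Per1, Per2, Per3, Dbp, Tef, Ciart, Nr1d1 and Nr1d2, repressors or outputs that these activators drive, rose. Per3 went from 6.95 ± 0.595 CPM with saline to 42.6 ± 3.32 CPM with baicalein (log2 fold change 2.62, SE 0.13, adjusted p = 5.86e-06). Dbp rose by a log2 fold change of 2.09 (SE 0.11) and Ciart by 3.41 (SE 0.41). Thus 8 of 11 tested members rose and 3 fell, the same when adjusted over the list alone (camera, up, adjusted p = 0.0108; adjusted p = 0.525 with an estimated correlation). Without baicalein 1 the list's adjusted p was 0.0532, the highest over 11 alternatives, the lowest being 0.00475. Clock lost its call without saline 2 or baicalein 1, Nr1d1 without saline 1, saline 2 or baicalein 1, and Nr1d2 without saline 1, baicalein 1 or baicalein 2, with adjusted p up to 0.106, 0.118 and 0.157.

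**Figure D2:**
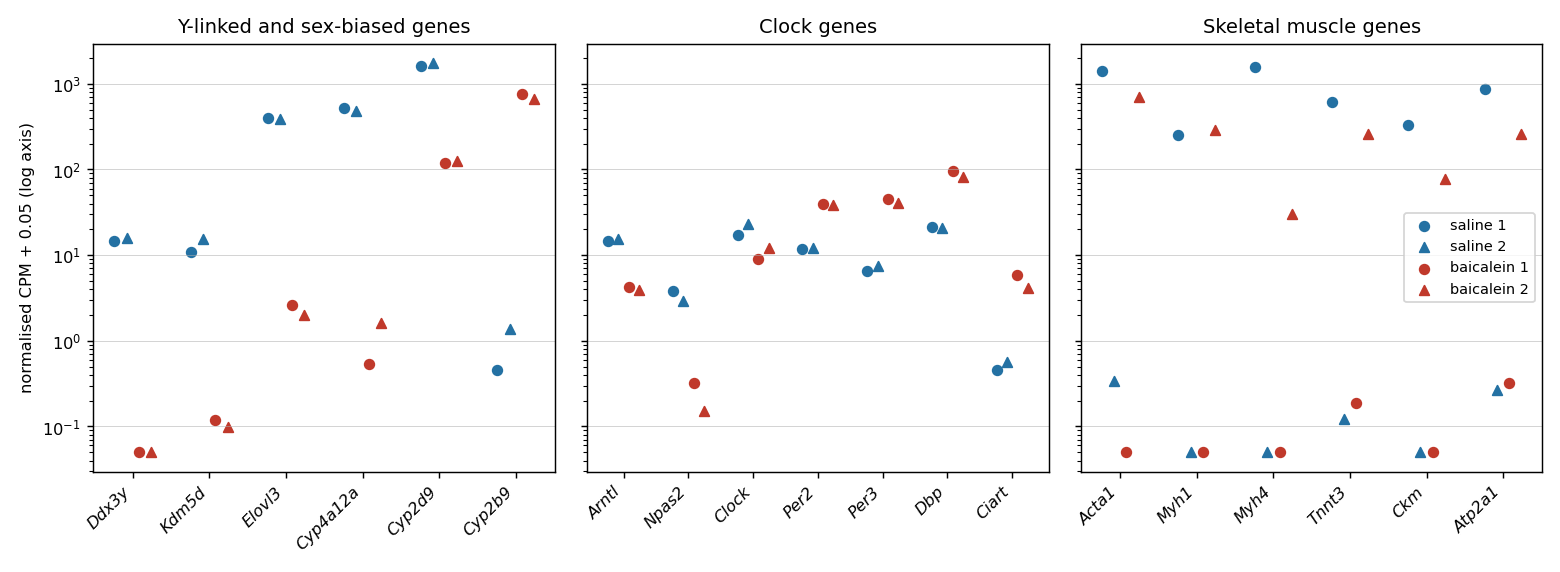
Each point is 1 liver, with normalised CPM plus 0.05 on a log axis for Y-linked and sex-biased genes, clock genes and skeletal muscle genes. The first 2 sets part saline from baicalein livers, while the muscle genes are high in saline 1 and baicalein 2 and near 0 in saline 2 and baicalein 1.

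The series title names TREM2-dependent polarization of macrophages, so Trem2 and genes of macrophage states were examined next. Trem2 (ENSMUSG00000023992, chromosome 17, 48653429 to 48661175) encodes a lipid-sensing receptor of macrophages. Its deposited counts were 2 and 4 with saline and 68 and 97 with baicalein, or 0.205 ± 0.123 CPM against 4.76 ± 0.116 CPM (SD, n = 2 each), a log2 fold change of 4.53 (SE 0.50, adjusted p = 5.77e-04). Tyrobp, the signalling adaptor of this receptor, was at 10.5 ± 0.451 CPM and 13.1 ± 2.04 CPM, a log2 fold change of 0.31 (SE 0.16, adjusted p = 0.250) that did not pass. The Trem2 value carries a limit that Creb1 shares, both being among 3 of the 21959 gene IDs whose counts and FPKM part. For every other gene the deposited FPKM equals the count divided by length and library total to within 3.48e-05%. The FPKM of Trem2 imply 2, 3.85, 60 and 111 reads in saline 1, saline 2, baicalein 1 and baicalein 2. The library totals behind the FPKM leave 146, 129, 132 and 211 reads for the 3 genes together, or 8.26, 9.23, 8.94 and 11.3 CPM. With the FPKM-implied counts the Trem2 log2 fold change was 4.55 (adjusted p = 6.55e-04), and over all alternatives its adjusted p ranged from 3.38e-12 to 0.0165. The log2 fold change ranged from 3.99 without saline 1 to 5.25 without saline 2, since the saline livers had 6 counts. Creb1, encoding a cAMP-responsive transcription factor, had deposited counts of 142, 118, 620 and 499 (log2 fold change 1.99, SE 0.31, adjusted p = 0.0276), a call lost without saline 1 or saline 2 (adjusted p up to 0.394). Its deposited 620 and 499 reads exceed the 132 and 211 that the totals leave for the 3 genes together in baicalein 1 and baicalein 2. By those totals the rise of Creb1 could not be of the size given. Creb1 was singled out after its values had been seen.

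**Figure D3:**
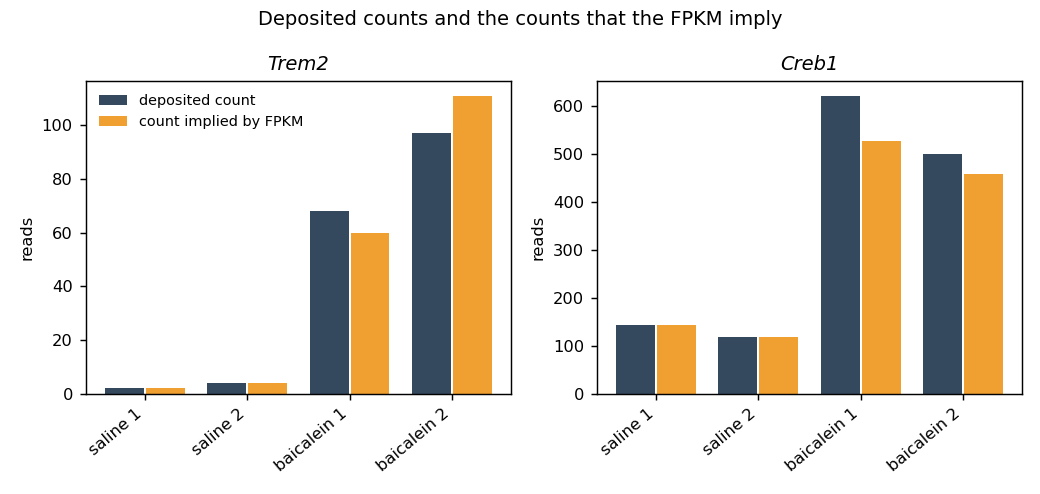
Bars give, for Trem2 and Creb1 in each liver, the deposited read count (dark) and the count that the deposited FPKM implies (orange), on axes that start at 0. The 2 bars match in saline 1 and part in both baicalein livers, for example 620 against 526 for Creb1 in baicalein 1.

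Among 16 tested TREM2-associated macrophage genes, 2 rose, 2 fell and 12 did not pass. Trem2 and Ctsb (log2 fold change 0.39, SE 0.10), a lysosomal protease gene, rose. Plin2, encoding a lipid droplet coat protein, fell from 903 ± 27.1 to 312 ± 20.7 CPM (log2 fold change -1.53, SE 0.11). Spp1, encoding osteopontin, also fell (log2 fold change -1.16, SE 0.11). As a list the genes did not stand apart (camera, adjusted p = 0.827; 3 rose and 2 fell when adjusted over the list alone). Without Trem2 itself, 1 of 15 rose and 2 fell, with a median log2 fold change of 0.07, a mean of -0.13 and a test direction of down (adjusted p = 0.871). Ctsb was not called without saline 1, saline 2 or baicalein 1, with adjusted p up to 0.435.

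Genes used as markers of alternatively activated (M2) macrophages included 3 that rose out of 13 tested. These were Arg1 (1024 ± 17.6 to 1767 ± 189 CPM, log2 fold change 0.79, SE 0.11, adjusted p = 0.00238), Cd163 and Il1rn. Cd163, a scavenger receptor gene, went from 17.7 ± 1.82 to 27.7 ± 3.61 CPM (log2 fold change 0.64, SE 0.14, adjusted p = 0.0153) and Il1rn, an interleukin 1 antagonist gene, rose by a log2 fold change of 1.19 (SE 0.25, adjusted p = 0.0132). Arg1 encodes arginase, which hepatocytes also express for the urea cycle. Mrc1, the mannose receptor gene, was at 32.5 ± 7.31 and 49.7 ± 2.26 CPM and did not pass (adjusted p = 0.0567), though it did without saline 1 (0.00486), with DESeq2, with no filter on low counts and with crosswise pairs. The list did not pass (camera, adjusted p = 0.152; 4 higher when adjusted over the list alone). It did pass among genes with a mean CPM of at least 1 (adjusted p = 0.0143, the lowest over 11 alternatives, with 0.589 the highest). Of 10 tested classically activated (M1) genes, Cd38 rose (log2 fold change 1.00, SE 0.10) and Socs3 fell (log2 fold change -0.78, SE 0.16), with 3 higher and 1 lower when adjusted over the list alone. The M1 list passed (camera, up, adjusted p = 0.0491; adjusted p = 0.525 with an estimated correlation), and not without saline 2 (0.268) or baicalein 1 (0.236), within a range of 0.0252 to 0.268. It did not pass with limma-voom (0.0896), no filter on low counts (0.178), a mean CPM of at least 1 (0.107), the replicate number as a block (0.0646) or crosswise pairs (0.104) either. Il1b gave a log2 fold change of -0.32 (SE 0.37, adjusted p = 0.620). Nos2, Tnf, Il6, Il10 and Chil3 had at most 11 counts in any liver, too few to be tested. Arg1 was not called without saline 1 or saline 2 (adjusted p up to 0.102), nor Cd163 without saline 2 or baicalein 1 (up to 0.122). The calls of Il1rn and Socs3 were lost, Il1rn without saline 1, baicalein 1 or baicalein 2 (up to 0.109) and Socs3 without saline 2 or baicalein 2 (up to 0.104).

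Markers of Kupffer cells, the resident macrophages of liver, were mostly higher with baicalein. Marco, a scavenger receptor gene, rose from 8.44 ± 0.790 to 28.1 ± 2.60 CPM (log2 fold change 1.73, SE 0.14, adjusted p = 9.25e-05). Vsig4 (log2 fold change 1.11, SE 0.15), Cd5l (1.07, SE 0.13) and Timd4 (0.99, SE 0.14) also rose. In all 8 of 12 rose and 1 fell, the same when adjusted over the list alone (camera, up, adjusted p = 0.00868; adjusted p = 0.525 with an estimated correlation). The member that fell, C6 (log2 fold change -3.68, SE 0.14), encodes a complement component and is also on the list of male-biased liver genes. Of the 8 that rose, Clec4f, Slc40a1, Adgre1 and Csf1r were not called without baicalein 1, which left 4, and 5 were left without saline 2. Without baicalein 1 the list's adjusted p was 0.0638, the highest over 11 alternatives, and the lowest was 0.00416. Among 10 genes for the uptake of dead cells, Mertk (log2 fold change 1.03, SE 0.11), Axl (0.85, SE 0.12), Itgb3 (1.54, SE 0.20) and Timd4 rose and none fell. These 10 are receptor genes together with Gas6, Mfge8 and Pros1, which encode secreted ligands. Over the list alone 6 were higher, and the list passed (camera, up, adjusted p = 0.00197; adjusted p = 0.407 with an estimated correlation). Of 9 monocyte and recruited macrophage markers, Lyz2 (0.87, SE 0.09) and Plac8 (1.67, SE 0.29) rose, 2 also over the list alone (camera, up, adjusted p = 0.00868; adjusted p = 0.407 with an estimated correlation). Plac8 lost its call without saline 1 or saline 2 (adjusted p up to 0.275). These macrophage lists moved between livers that also differed in Y-linked counts (820 and 836 against 2 and 1).

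Lymphoid and endothelial markers were higher as lists too. Of 10 sinusoidal endothelial markers, 8 rose and none fell (9 when adjusted over the list alone). Among them were Stab2 (69.0 ± 2.41 to 104 ± 1.47 CPM, log2 fold change 0.59, SE 0.09), Bmp2 (1.06, SE 0.12) and Ptprb (0.90, SE 0.12). These 3 were the only ones still called without saline 2, where Clec4g, Fcgr2b, Kdr, Lyve1 and Oit3 were lost, and 4 were left without baicalein 1. The list had the smallest p of the 36 (camera, up, adjusted p = 2.02e-04; adjusted p = 0.444 with an estimated correlation). Of 6 B and plasma cell markers, Jchain, the joining chain of secreted immunoglobulin, rose from 0.798 ± 0.201 to 6.39 ± 0.783 CPM (log2 fold change 2.98, SE 0.34). Over the list alone 3 were higher, and the list passed (camera, up, adjusted p = 8.08e-04; adjusted p = 0.407 with an estimated correlation). Of 11 T and NK cell markers, Gzma, encoding a granule protease, was the 1 that rose (log2 fold change 1.94, SE 0.49), also over the list alone. The list passed (camera, up, adjusted p = 0.00591; adjusted p = 0.407 with an estimated correlation). Gzma lost its call when any of the 4 livers was left out (adjusted p up to 0.204). Of 8 neutrophil markers, Ltf (3.71, SE 0.69) and Lcn2 (0.89, SE 0.20) rose, also over the list alone, at levels of at most 11.3 CPM (camera, adjusted p = 0.109). Ltf lost its call without saline 1, saline 2 or baicalein 2 and Lcn2 without saline 1, saline 2 or baicalein 1 (adjusted p up to 0.124 and 0.153). With no filter on low counts (adjusted p = 0.0385) or without baicalein 2 the list passed (adjusted p = 0.0103, the lowest over its alternatives, with 0.673 the highest). Red blood cell genes went the other way: 4 of 5 fell, and 5 over the list alone (camera, down, adjusted p = 2.02e-04; adjusted p = 0.407 with an estimated correlation). Alas2, the heme synthesis enzyme of red cell precursors, fell from 153 ± 15.2 to 21.8 ± 1.71 CPM (log2 fold change -2.81, SE 0.12). Hba-a1, a hemoglobin gene, had a log2 fold change of -2.45 (SE 0.23), a call lost without baicalein 1 or baicalein 2 (adjusted p up to 0.114). Hbb-bs was lost in the same way (up to 0.150) and Hbb-bt without baicalein 2 (0.0524), so Alas2 alone was called there.

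Skeletal muscle transcripts were abundant in 2 of the 4 livers, 1 of each group. A set of 16 skeletal muscle genes, written after the values were seen, had 121652 counts in saline 1 and 49723 in baicalein 2, against 21 in saline 2 and 17 in baicalein 1. They made up 0.688% of all counts in saline 1 and 0.265% in baicalein 2. None of the 16 passed between the groups. Col1a1, encoding a chain of type I collagen, was at 130 and 101 CPM in the livers with muscle transcripts and at 32.7 and 28.7 CPM in the others (log2 fold change -0.32, SE 1.25, adjusted p = 0.915). Its sign turned without saline 1 (0.99) or baicalein 1 (0.31). Acta2, the smooth muscle actin gene of activated stellate cells, was at 101 CPM in baicalein 2 and at 13.1, 4.81 and 3.99 CPM in saline 1, saline 2 and baicalein 1 (log2 fold change 2.55, SE 2.14, adjusted p = 0.568). It turned to -1.16 without baicalein 2. None of 5 tested smooth muscle genes, also listed afterwards, passed. Timp1 had 0, 1, 4 and 8 counts, too few to be tested.

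Of 16 stellate cell and fibrosis genes, 5 rose, with none lower and 6 higher when adjusted over the list alone. Dcn, encoding the proteoglycan decorin, rose from 67.3 ± 3.96 to 171 ± 2.14 CPM (log2 fold change 1.34, SE 0.10), and Lrat, which stores retinol as esters in stellate cells, by 2.44 (SE 0.26, not called with the replicate number as a block, adjusted p = 0.0649). The list passed (camera, up, adjusted p = 0.0124; adjusted p = 0.525 with an estimated correlation), but not without saline 2 (0.201) or baicalein 2 (0.172), within a range of 6.11e-04 to 0.201. The median log2 fold change of its members was 0.43 between saline 2 and baicalein 1, the livers with few muscle counts, and 0.68 between saline 1 and baicalein 2. With all 4 livers it was 0.50, and it fell to 0.15 without saline 2 and to -0.21 without baicalein 2. Postn, Lum and Pdgfrb also rose, but Postn was not called without baicalein 2 (adjusted p = 0.0520). Lum lost its call without saline 1, saline 2 or baicalein 2 (up to 0.271) and Pdgfrb without saline 1, baicalein 1 or baicalein 2 (up to 0.248). Of 8 cholangiocyte markers, 3 fell, Spp1 and Sox9 (log2 fold change -1.16, SE 0.22) among them, and none rose, also over the list alone (camera, adjusted p = 0.732). The median was 2.03 although the test pointed down, because Krt19, Krt7, Epcam, Cldn7 and Prom1 were far higher in baicalein 2 than in the other livers, Krt19 being at 72.2 CPM there and at most 2.29 CPM elsewhere. Sox9 lost its call without saline 1 or baicalein 1 (adjusted p up to 0.0734).

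Hepatocyte genes changed in both directions. Alb, encoding albumin, rose from 54510 ± 1914 to 81019 ± 9558 CPM (log2 fold change 0.57, SE 0.14, adjusted p = 0.0237). Cps1 (0.60, SE 0.11) rose too, while Apob (-0.61, SE 0.13) and Tat (-0.40, SE 0.11) fell. Of 13 hepatocyte markers 3 rose and 2 fell, and 3 and 3 over the list alone (camera, adjusted p = 0.874). None of the 5 calls in this list held without saline 1 or without saline 2, with adjusted p up to 0.457 for Alb. Among 10 urea cycle and gluconeogenesis genes, Arg1, Cps1, Gls2, Asl and Ass1 rose and G6pc fell (log2 fold change -1.77, SE 0.27), and 6 rose and 1 fell over the list alone (camera, adjusted p = 0.173). Gls2, Asl and Ass1 lost their calls without saline 1, saline 2 or baicalein 1 (adjusted p up to 0.508) and G6pc without baicalein 1 or baicalein 2 (up to 0.317). Saa1 (ENSMUSG00000074115, chromosome 7, 46389921 to 46392404), an acute phase gene, fell from 96.9 ± 13.1 to 22.2 ± 0.868 CPM (log2 fold change -2.12, SE 0.12, adjusted p = 9.89e-06) and its near-identical neighbour Saa2 by -1.09 (SE 0.12). Of 17 acute phase genes, Lcn2, Itih4 and Orm2 rose and 5 fell, 4 and 5 over the list alone, and the list did not pass (camera, adjusted p = 0.183). Of the 3 that rose, none was called without saline 1 (adjusted p up to 0.334 for Itih4, 0.240 for Orm2 and 0.153 for Lcn2 over the livers left out). Of the 5 that fell, only Saa1 and Saa2 were called without saline 2, where Socs3, Orm1 and Saa3 were lost, Saa3 also without any other 1 of the livers.

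Genes of bile acid synthesis were split. Cyp7a1, the rate-limiting enzyme of the classical pathway, rose from 9.43 ± 0.281 to 52.0 ± 9.58 CPM (log2 fold change 2.46, SE 0.15, adjusted p = 1.86e-05). Cyp7b1, of the alternative pathway, fell from 244 ± 34.0 to 18.8 ± 0.177 CPM (log2 fold change -3.70, SE 0.13, adjusted p = 6.06e-07), and Cyp8b1, the sterol hydroxylase for cholic acid, by -2.23 (SE 0.16). Of 14 tested genes of bile acid synthesis and transport, 1 rose and 6 fell, and 3 and 7 over the list alone (camera, down, adjusted p = 0.0149; adjusted p = 0.525 with an estimated correlation). Cyp7b1 and the transporter gene Slco1a1 (-2.21, SE 0.18, not called without baicalein 1 or baicalein 2, up to 0.0776) are also on the list of male-biased liver genes. Cyp27a1 and Abcc3 were not called without saline 1 or saline 2, which left 4 of the 6 that fell. Without baicalein 2 the list's adjusted p was 0.0656, the highest over 11 alternatives, with 0.00704 the lowest. Of 12 cytochrome P450 drug metabolism genes, 6 rose and 3 fell, with 7 and 3 over the list alone. Cyp2a5 (log2 fold change 1.75, SE 0.11) and Por (1.20, SE 0.11) were among those that rose, and Cyp3a11 (-1.31, SE 0.12) and Cyp2f2 (-1.10, SE 0.11) among those that fell. Without saline 1 or baicalein 1, 4 of the 6 and 2 of the 3 kept their calls. This list did not pass (camera, adjusted p = 0.0629), though it did with limma-voom or without baicalein 2 (0.0389) in a range of 0.0330 to 0.236. Cyp1a1, the best known target of the aryl hydrocarbon receptor, which flavones can bind, was at 1.77 ± 0.237 and 2.63 ± 0.309 CPM (adjusted p = 0.362). Of 5 such targets Nqo1 rose, the 1 call also over the list alone, and the list passed (camera, up, adjusted p = 0.0370; adjusted p = 0.407 with an estimated correlation). The call of these 5 was lost without baicalein 1 (0.0924) or baicalein 2 (0.0656), against 0.0149 at the lowest.

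Lipid genes moved apart by function. Srebf1, the lipogenic transcription factor gene, rose from 161 ± 23.9 to 410 ± 43.6 CPM (log2 fold change 1.34, SE 0.13), with Fasn (1.20, SE 0.14), Thrsp (1.32, SE 0.13) and Elovl6 (0.81, SE 0.12). Of 9 fatty acid synthesis genes 7 rose and 1, Me1, fell, the same over the list alone (camera, up, adjusted p = 0.00727; adjusted p = 0.525 with an estimated correlation). Acaca, Acly and Pnpla3 lost their calls without saline 1 or saline 2 (adjusted p up to 0.193, 0.163 and 0.0956), which left 4 of the 7. Of 13 fatty acid oxidation genes 4 fell, among them Acaa1b (-0.78, SE 0.10) of the peroxisome, and Cyp4a14 rose (1.22, SE 0.19). Over the list alone 5 were lower and 1 higher, and the list passed (camera, down, adjusted p = 0.0198; adjusted p = 0.407 with an estimated correlation). This call was lost without saline 2 (adjusted p = 0.0881, the highest of a range from 0.0107), and that of Me1 without saline 1 or saline 2 (up to 0.0794). Of the 4 oxidation genes that fell, 1 was still called without saline 1 or saline 2. Of 13 cholesterol synthesis genes, 3 rose, Sqle (0.68, SE 0.15) among them, and none fell, also over the list alone (camera, adjusted p = 0.142). This list passed without baicalein 2 (0.00358) in a range up to 0.965, and Sqle was not called without saline 1, saline 2 or baicalein 1 (up to 0.193). Of 11 tested mitochondrially encoded genes, mt-Co2 (-0.59, SE 0.09) and mt-Nd1 fell, 2 also over the list alone (camera, down, adjusted p = 0.00836; adjusted p = 0.407 with an estimated correlation). Mitochondrial genes took 4.28% and 3.54% of counts in the saline and 3.34% and 3.17% in the baicalein livers. The mt-Nd1 decrease was not called without saline 1 or saline 2 (adjusted p up to 0.469).

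Antioxidant genes driven by NRF2 were mostly lower with baicalein. Gclc, the catalytic subunit gene of glutathione synthesis, fell from 696 ± 7.70 to 269 ± 7.40 CPM (log2 fold change -1.37, SE 0.10, adjusted p = 5.32e-05). Osgin1 changed by -1.93 (SE 0.14), Txnrd1 by -0.70 (SE 0.10) and Srxn1 by -0.64 (SE 0.10). Of 11 members 6 fell and Nqo1 rose (1.20, SE 0.21), and 7 and 1 over the list alone (camera, down, adjusted p = 0.00417; adjusted p = 0.407 with an estimated correlation). Nqo1 lost its call without baicalein 1 (adjusted p = 0.0832), and Gclm and Gstm1 without saline 1, saline 2 or baicalein 2, which left 4 of the 6. Of 9 immediate early genes, Jun (-1.40, SE 0.09), Dusp1 (-1.29, SE 0.12) and Egr1 (-0.98, SE 0.11) fell and none rose, also over the list alone. The list passed (camera, down, adjusted p = 0.0394; adjusted p = 0.407 with an estimated correlation). That list was lost without saline 1 (0.0985) or baicalein 1 (0.0924), or with the replicate number as a block (0.0629), in a range from 0.00625. Among 13 cell cycle genes, Ccnb2, Cdk1 and Mcm5 fell. Ccnd1, encoding cyclin D1, rose from 22.9 ± 4.95 to 65.3 ± 0.623 CPM (log2 fold change 1.51, SE 0.15). Over the list alone 5 were lower and 1 higher, and the list passed (camera, down, adjusted p = 0.00666; adjusted p = 0.407 with an estimated correlation). The decreases of Ccnb2, Cdk1 and Mcm5 were lost when any of the 4 livers was left out (adjusted p up to 0.431, 0.312 and 0.187).

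Inflammatory gene lists were higher or did not pass, with few single genes past the test. Of 14 interferon response genes, Oas1a (log2 fold change 1.01, SE 0.17), Ifi44 and Ifit3 rose, 5 over the list alone (camera, up, adjusted p = 0.00640; adjusted p = 0.407 with an estimated correlation). The list was lost without baicalein 1 (0.0904, in a range from 0.00215). Vcam1, an adhesion molecule gene, rose from 11.5 ± 0.00908 to 29.8 ± 0.315 CPM (log2 fold change 1.38, SE 0.12). With Cxcl1 and Icam1 it made 3 of 9 NF-kappaB target and chemokine genes that rose, also over the list alone (camera, up, adjusted p = 0.0236; adjusted p = 0.525 with an estimated correlation). That call was lost without saline 2 (0.589), baicalein 1 (0.210) or baicalein 2 (0.0583), or with no filter on low counts (0.156), in a range from 0.00722, and the median log2 fold change of the list was -0.02 without saline 2. Of 11 antigen presentation genes Psmb9 (0.72, SE 0.11), Psmb8 and H2-D1 rose, 4 over the list alone (camera, adjusted p = 0.0615). The list passed with limma-voom or without baicalein 2 (0.0389, in a range of 0.0270 to 0.236). None of 9 inflammasome and pyroptosis genes passed, in either adjustment (camera, adjusted p = 0.0787), though that list did without saline 2 (0.0195, in a range up to 0.143). Oas1a lost its call without baicalein 1 (0.0522), Psmb8 and Icam1 without any 1 of the 4 livers (up to 0.126 and 0.196), and H2-D1 without saline 1, saline 2 or baicalein 1 (up to 0.387). Cxcl1 was not called without saline 2 or baicalein 1 (up to 0.113), nor Ifi44 without saline 1, baicalein 1 or baicalein 2 (up to 0.129), nor Ifit3 without saline 1, saline 2 or baicalein 2 (up to 0.102).

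Lists of stress genes did not pass. Of 10 endoplasmic reticulum stress genes, Hspa5 (log2 fold change 0.58, SE 0.10), Dnajb9 and Xbp1 rose and Atf3 (-1.53, SE 0.20) and Atf4 (-0.53, SE 0.10) fell, with 4 higher and 2 lower over the list alone. The median was 0.22 and the mean -0.06 (camera, adjusted p = 0.669). Of 7 heat shock genes, Hspa8 (0.52, SE 0.10) and Hsph1 (0.88, SE 0.15) rose, also over the list alone, while the median was -0.04 and the test pointed up (camera, adjusted p = 0.895). Hsph1 was not called with the replicate number as a block (adjusted p = 0.0981). Hspa5, Hspa8, Xbp1 and Dnajb9 were not called without saline 1 or saline 2 (adjusted p up to 0.386, for Xbp1), nor Atf4 without saline 2 or baicalein 2 (0.0608). None of 11 p53 and cell death genes passed in either adjustment (camera, adjusted p = 0.291). Only 2 exocrine pancreas genes had enough counts, of which Cela1 fell by -0.44 (SE 0.12), also over the list alone (camera, adjusted p = 0.291), a call lost without any 1 of the 4 livers (up to 0.208). Over all 36 lists fixed before the data were examined, 21 passed camera with its preset correlation, 0 with an estimated correlation (smallest adjusted p 0.407) and 8 passed fry's directional test. Those 8 were the sex-linked, red blood cell, B and plasma cell, NRF2, cell cycle, clock, aryl hydrocarbon receptor and immediate early lists. The other lists past camera did not pass fry, among them Kupffer cell (fry, adjusted p = 0.157), dead cell uptake (0.0624), monocyte (0.0911), M1 (0.0848), sinusoidal endothelial (0.0571) and stellate cell genes (0.385). With 4 livers, camera with an estimated correlation could hardly pass any list. B and plasma cell markers did not pass it although their estimated correlation was -0.197. Not passing it therefore does not show that correlation between members accounts for a list. Nor is that excluded. The estimate was far above the preset 0.01 for fatty acid synthesis (0.735), Kupffer cell (0.553), stellate cell (0.451) and sinusoidal endothelial genes (0.419), among others. For such lists the p with the preset correlation may be too small. It was below 0.01 for monocyte, cell cycle, fatty acid oxidation, aryl hydrocarbon receptor, mitochondrial and immediate early genes. The livers compared in every list also differed in Y-linked counts (820 and 836 with saline, 2 and 1 with baicalein).

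**Figure D4:**
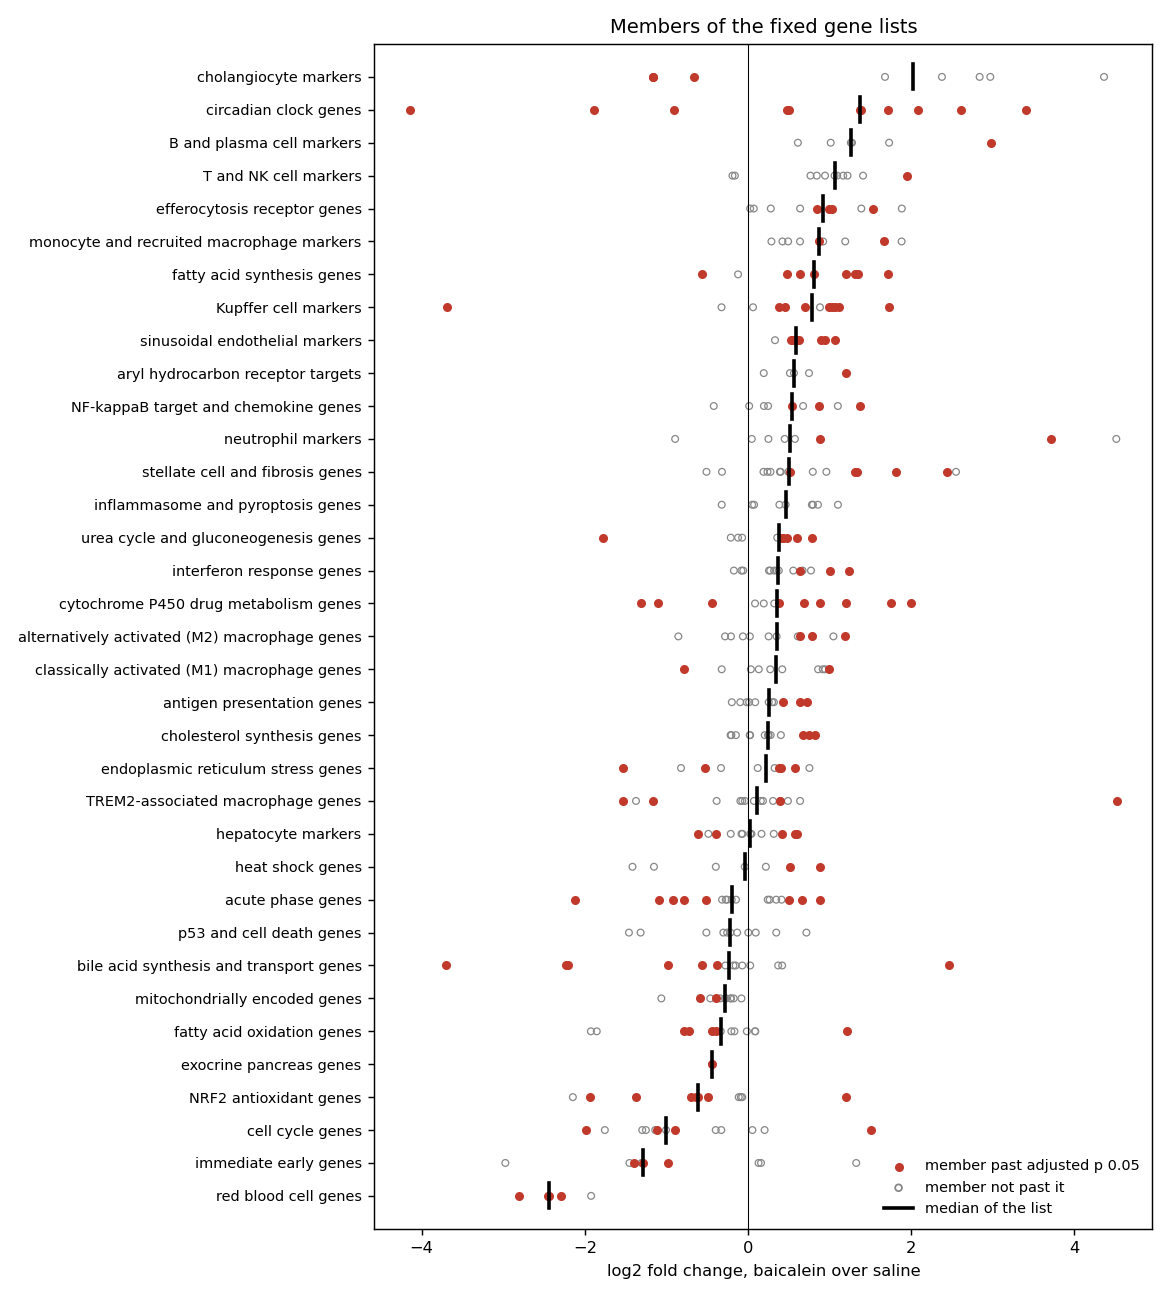
Each row is 1 of the fixed gene lists except the sex-linked list, each point is a tested member at its log2 fold change, baicalein over saline, and the black bar is the median of the list. Filled red points passed adjusted p below 0.05, open grey points did not, and the medians run from -2.45 for red blood cell genes to 2.03 for cholangiocyte markers.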

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

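Both tests in this part were chosen after the result they bear on was seen. The deposited FPKM, which the main fit does not use, gave values for 3 genes that the counts do not. For Trem2 the FPKM imply 3.85 reads in saline 2, 60 in baicalein 1 and 111 in baicalein 2, where the deposited counts are 4, 68 and 97. For Creb1 they imply 526 and 456 reads in baicalein 1 and baicalein 2, where the counts are 620 and 499. The column sum of the counts minus the library total behind the FPKM was -4 in saline 2, 572 in baicalein 1 and 397 in baicalein 2, and 0 in saline 1, where all 3 genes match.

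A gene length other than the one in the table would shift all 4 livers of a gene alike, but the ratio of implied to deposited count differed between the livers of Trem2 by 1.30 times, which argues against it. Counts entered or changed after the FPKM were computed would leave the totals off in the livers with a mismatch. They would leave the total exact in the liver without one. This held in 4 of 4 livers, so such a change stays a candidate, though not as the only change. A change of the FPKM of these genes alone would have left the totals exact. After a change of the counts alone, the FPKM-implied counts would restore the totals. They do not: those of Creb1 alone exceed the 132 and 211 reads that the totals leave for the 3 genes in baicalein 1 and baicalein 2. This argues against a change of the counts alone. Nothing here shows which of the 3 sets of values was measured, and no biological explanation was tested, since treatment acts on a count and its FPKM alike. The raw reads, which would decide the level of Trem2, were not analysed here.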

How the results depend on the processing

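The crosswise block and the FPKM-implied counts were chosen after seeing the data, the other alternatives before. Of 968 genes higher and 1000 lower, limma-voom called 632 higher, the replicate block 531 higher and 601 lower, and leaving out 1 liver 521 to 665 higher and 535 to 663 lower. The lone liver then left in a group was taken to vary like the other group. A fold of at least 2 left 381 of the 968 and 244 of the 1000 at the adjusted threshold. With that fold and an unadjusted p below 0.05 there were 606 higher and 293 lower, some of them not among the 968 and 1000. The livers' numbers do not pair them (correlation of deviations -0.77 for the same number), and 1121 of the 1132 genes called with the replicate block were also called without it. Crosswise pairs gave 1809 higher and 1689 lower, of which 1967 were called without a block. These pairs put the livers with skeletal muscle transcripts, saline 1 and baicalein 2, in 1 block and the livers without them in the other. The replicate block instead joins a liver with and a liver without such transcripts, so calls lost with it may partly reflect muscle. With the settings not named here both counts stayed within 1.5 times, and Trem2 kept its call in all settings. Fewer livers leave fewer degrees of freedom for the spread; the cause of the other differences was not tested.

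The median log2 fold change of the M1 list was 0.346 with limma-voom, 0.191 without a filter, 0.279 at a mean CPM of at least 1, 0.347 with the replicate block, 0.347 with crosswise pairs, all short of the threshold, and 0.198 to 0.370 with a liver left out. The M2 list passed at a mean CPM of at least 1 (median 0.633), where fewer genes were tested. The test direction turned for lists that never passed. Without a filter, medians were -0.0512 for heat shock genes, 0.0166 for hepatocyte markers and 0.0563 for TREM2-associated genes. With crosswise pairs they were 1.83 for cholangiocyte markers, -0.0388 for heat shock genes and 0.0280 for hepatocyte markers, and with the replicate block -0.0383 for heat shock genes. With a liver left out, medians ran from -0.386 to 2.78 for cholangiocyte markers, -0.391 to 0.850 for exocrine pancreas genes, -0.0810 to -0.00946 for heat shock genes, -0.0965 to 0.105 for hepatocyte markers and -0.0356 to 0.160 for TREM2-associated genes. The log2 fold changes of Col1a1, Acta2 and Cela2a, called only for Col1a1 with crosswise pairs, ran from -1.495 to 0.99, -1.16 to 3.48 and -1.08 to 0.85. Over all lists and alternatives, 349 list results kept direction and side, 23 weakened, 9 strengthened and 15 turned; of named genes, 2165 kept them, 389 weakened, 37 strengthened and 4 turned. Depth limits genes such as Nos2, Tnf, Il6, Il10 and Timp1, with at most 11 counts in a liver.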

Other observations

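The pathway tests, the 3 splits of the livers and the count of groups with both Y-linked patterns were chosen after results had been seen, the X-linked, clock output and muscle tests before their values were. Among genes lower with baicalein, peroxisomal genes stood out: 33 of 80 tested members of the KEGG peroxisome pathway were lower, where 7.57 were expected (one-sided Fisher exact test, adjusted p = 1.70e-11 over 608 tests). Fatty acid degradation (19 of 45, adjusted p = 7.18e-07), glutathione metabolism (17 of 57, adjusted p = 4.11e-04) and oxidative phosphorylation (25 of 108, adjusted p = 5.61e-04) were also enriched among lower genes. Retinol metabolism was enriched both among higher (28 of 77, adjusted p = 2.59e-08) and among lower genes (25 of 77, adjusted p = 1.51e-06), as was steroid hormone biosynthesis (22 and 23 of 63), and both pathways hold many sex-biased P450 genes. Arginine biosynthesis (8 of 17, adjusted p = 0.00189), cell adhesion molecules (23 of 102, adjusted p = 0.00156) and phagocytosis through Fc gamma receptors (18 of 81, adjusted p = 0.00806) were enriched among higher genes. Of 304 pathways tested in both directions, 47 tests passed. Genes are not independent, so these p-values describe the called genes and not the treatment.

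The groups differed in sex-linked, sex-biased and clock genes at the same time as in treatment. A hypothesis is that the saline livers came from male and the baicalein livers from female mice. Then X-linked genes that escape inactivation should be higher with baicalein, and Kdm6a, Kdm5c, Ddx3x and Eif2s3x had log2 fold changes of 0.52, 0.31, 0.21 and 0.79 (median 0.414, 4 of 4 above 0, 2 called, 1 of the 2 each time a liver was left out), which is consistent with it. The Y-linked counts prompted the hypothesis and are not a separate test of it. At 820 and 836 with saline against 2 and 1 with baicalein, they argue against livers of the same sex in both groups. The livers may also have been taken at different phases of the clock: 4 of 5 other clock outputs moved in the direction named beforehand (Nfil3 -1.07, Cry1 -0.25, Wee1 0.52, Usp2 1.77, but Bhlhe41 -0.38), though only Nfil3 passed and an effect of sex or baicalein on the clock stays open, untested. An effect of baicalein on the remaining genes cannot be told apart from these differences, since 0 of the 2 groups held livers of both Y-linked patterns.

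Skeletal muscle genes were high in 1 library of each group. Pieces of muscle in these samples may account for it: 11 of 12 muscle genes of a second list, written when the first had been seen but not the values of these, were over 10 times higher in both than in the other liver of the same group. The 16 genes of the first list made up 0.688% of counts in saline 1 and 0.265% in baicalein 2. The high Krt19 and Myh11 of baicalein 2 are not skeletal muscle genes, so other tissue in that sample, such as a large bile duct with its wall, is a further candidate source that was not tested.

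Grouping the 4 livers in other ways gave far fewer genes, which the design favours. Each other split puts a saline and a baicalein liver on both sides, so the difference between the groups becomes spread within a side. The numbers of calls therefore do not test whether the real split stands apart by chance. The real split called 1968 and the highest of the others 25, for the livers with against those without muscle counts, and 1 of the 3 splits (the real one) gave as many, too few splits for a share under 0.05. The split by number called 0 genes with edgeR, where 17 had an unadjusted p below 0.05.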
